A study of Mus musculus with 4 samples.

How the data were processed

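Colonic mucosa was scraped after incubation of the colon in 4 mM EDTA with 10% serum for 30 min, per the labels' protocols, and nuclei were bound to beads, incubated with an antibody against Fos and tagmented with protein A/G-Tn5. The 4 libraries were 2 healthy controls and 2 colitis recovered animals, all with the same batch label. Whether the libraries came from separate animals is given only through their labels as replicates. No library of an untargeted antibody or other background control was used here, so the contribution of open chromatin that Tn5 cuts without Fos was not measured.

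Reads were aligned with Bowtie2 to mm10 and peaks called with MACS2, per the submitters' processing notes, which give no version, command or order. The deposited file was 1 list of summits in the narrowPeak layout for the whole series, with no column per library. Which of the 4 libraries entered the list, how they were combined and how duplicate reads were treated were not given in the sources used here. The authors' score column held the integer part of 10 times the −log10 q. The deposited fold enrichment at each summit is a linear ratio over background, and the authors' −log10 p-value and −log10 q-value columns hold the caller's statistics. The lowest −log10 q was 1.80. These values are the authors' and were used only to describe, rank and filter summits within the list.

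All folds were whole multiples of 0.2405 within a tolerance of 0.05 steps, the step expected of (pileup + 1) over (background + 1) with a single background of 3.16 fragments per base, and the pileup in whole fragments was read from it. A Poisson −log10 p recomputed from that pileup matched the deposited −log10 p-value within 0.01 at 100% of the 167414 summits where it could be computed. Depth per library remains unknown. The interval of a pileup is an exact 95% Poisson interval and that of a share a 95% Wilson interval, both for counting error only, since fragments copied by PCR are not independent molecules.

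Gene positions came from an NCBI RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 21627 protein-coding genes on the autosomes and chromosome X. Positions are 1-based. The table gives the start and end of each gene but no strand and no exons, and no genome sequence was used here. The tests of AP-1 and other motifs at summits, of motif share by strength and between promoter and distal summits, and of genomic motif occurrences inside peaks were planned and were not run. Promoters were replaced by both boundaries of a gene, within 1000 bp. Distal summits with a motif were replaced by all summits not at any boundary, inside the gene or within 50 kb of its span. Exons and introns were not told apart. Summits at a boundary came before those in gene interiors and then intergenic ones. The share of bases was counted from position 3000001 of each chromosome to the last gene or region.

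The 24 gene lists, with 376 distinct genes, all of which matched the gene table, the rule for named genes and the design of each test were written before the data were examined. Boundary summits in list members were compared with all other protein-coding genes by Fisher's exact test, two-sided. That comparison was not matched on gene density, gene length or gene activity. The mean number of distal summits of a list was compared with 10000 random lists of the same size, drawn from the same 5 bins of gene density, by a two-sided permutation test whose smallest p is 0.0002. Both were adjusted by Benjamini-Hochberg over the 24 lists, with a threshold of 0.05. Matching on gene length as well was tried first and gave 7 lists. For the matching, the design written beforehand names gene density alone, so that is the main result and the other an alternative. The window was not as planned. The design counted within 50 kb of the start of transcription, which the gene table does not give, and the span used instead grows with gene length. Windows around both boundaries, which do not, also gave 7 lists. The rule named every AP-1 list gene, the 3 genes of each other list with the most distal summits, and the 10 strongest regions of at most 1000 bp. Its condition that these hold a motif could not be applied, and some genes it names are not reported here. Other genes named, such as those without a boundary summit, were chosen after their values were seen.

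In tests on simulated data with the 21627 genes, pileups were recovered at 100% of 20000 summits. With the boundary share of a list raised to 98%, the boundary test called 72.5% of 80 changed lists and 0.760% of 395 unchanged ones. With distal counts multiplied by 2 and raised by 3, the distal test called 55% of 80 changed lists and 1.27% of 395 unchanged ones. Distal counts were first shuffled among genes of the same density bin. That removed the effects of gene length and of overlapping windows, so false calls from these were not measured. A list that did not pass may therefore still differ. Alternatives were stricter limits of −log10 q (5 and 10), 1 summit per region, no regions wider than 3000 bp, autosomes only, boundaries of 500 and 2000 bp, windows of 20 and 100 kb and matching on gene length. Chosen after seeing the data were matching on density and length together, windows around both boundaries, genes with boundaries more than 2000 bp from those of other genes, 1 gene per locus, and leaving out the 20 widest regions and a ribosomal RNA region. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.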

Results

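The series profiled Fos in mouse colonic epithelium by CUT&Tag, an assay in which an antibody against the protein directs the transposase Tn5 to cut and tag the DNA around it. Fos is a subunit of AP-1, the family of leucine zipper transcription factors induced by growth signals, stress and injury. Of the 4 libraries, 2 came from healthy controls and 2 from animals that had recovered from colitis. The recovered animals had received 1 to 1.5% dextran sodium sulfate (DSS), a polymer that injures the colonic epithelium, in 3 cycles of 7 days with 10 days off, and were killed 22 days after the last cycle. All 4 libraries carried the same batch label. The stated purpose was to map Fos sites in both tissues and to compare them with computational predictions.

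The file analysed was 1 MACS2 peak list for the whole series in mm10 coordinates, without values per library. Healthy and recovered colon therefore could not be compared here, and no value below has a replicate error. Which of the 4 libraries entered the list, and the number of reads per library, were not given in the sources used here. The fold enrichments recorded by the authors showed a background of 3.16 fragments per base, from which the number of overlapping fragments at every summit (the pileup) followed. Intervals on pileups and shares cover counting error only, and those on shares of summits treat summits of the same region as independent.

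Fos signal was called at 178981 summits in 108406 regions, which covered 84.0 Mb on the 19 autosomes and chromosome X. The median region was 527 bp wide, with an interquartile range of 303 to 968 bp, and 34.0% of regions held more than 1 summit. The median summit had a fold enrichment of 6.73 (interquartile range 4.09 to 15.4) and a pileup of 27 fragments. The weakest summit had 10 fragments and the strongest 2791. Chromosome X carried 14.2 summits per Mb against 73.5 per Mb on the autosomes, and 332 of its 966 protein-coding genes (34.4%, 95% Wilson interval 31.4 to 37.4) had a summit within 1 kb of a gene boundary, against 63.3% (62.6 to 63.9) of autosomal genes.

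Fos summits lay at gene boundaries far more often than the bases there would give. Without a control library, the part of this due to open chromatin that Tn5 cuts without Fos was not measured. The same limit holds for every list, family and gene below. Because the gene table carried no strand, a boundary here means either end of a protein-coding gene, start and end of transcription alike. Summits within 1 kb of a boundary numbered 31046, or 17.3% (17.2 to 17.5) of all, while such bases made up 3.03% of the chromosomes, a 5.72-fold enrichment. Gene interiors held 84491 summits (47.2%) on 38.3% of bases, and intergenic sequence held 63444 (35.4%) on 58.7% of bases, a ratio of 0.604. When summits were ranked by fold and parted into 10 bins of equal size, the boundary share rose with every bin, from 9.84% (9.41 to 10.3) in the weakest to 29.9% (29.2 to 30.5) in the strongest. Boundary summits were also stronger, with a median pileup of 42 fragments against 25 in both other classes. Most summits of the strongest bin, 6856 in gene interiors and 5696 in intergenic sequence against 5346 at boundaries, still lay away from boundaries. With 1 summit per region the boundary share was 13.2%, outside the 17.2 to 17.5 given for all summits, and the enrichment was 4.36-fold. The ratio of the median pileup of boundary summits to that of the rest then rose from 1.68 to 2.92.

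**Figure D1:**
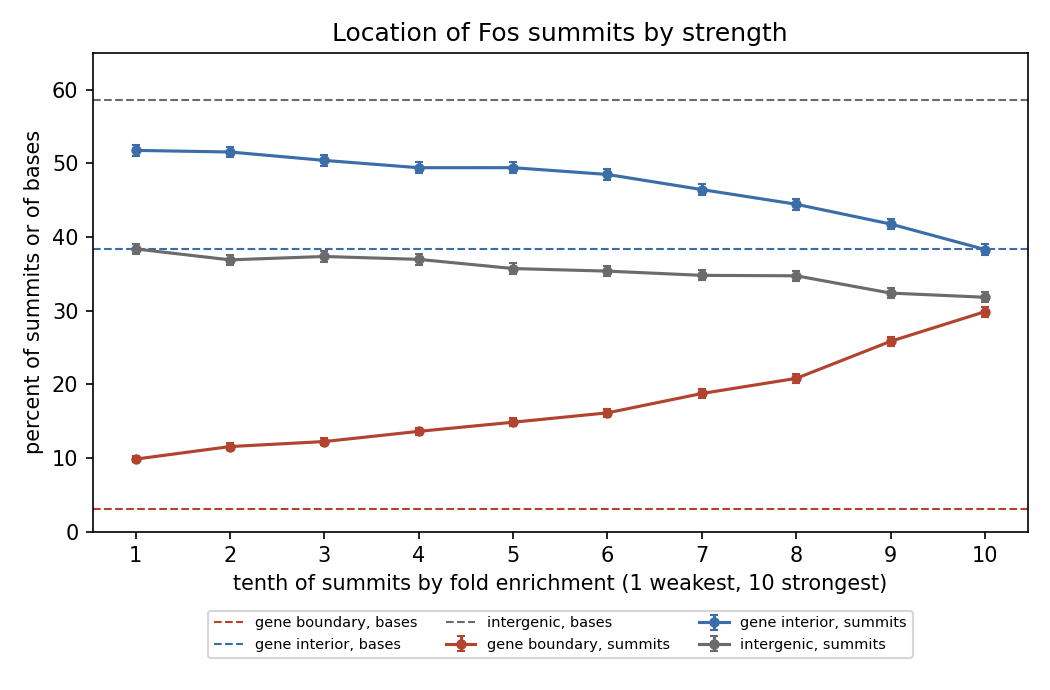
Percent of Fos summits (vertical axis) in 10 bins of equal size ranked by fold enrichment (horizontal axis), for gene boundaries, gene interiors and intergenic sequence; points carry 95% Wilson intervals and dashed lines give each class's percent of bases. The boundary share rises from 9.84% to 29.9%, and the interior share falls from 51.8% to 38.3%.

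The strongest narrow sites, ranked by fold alone, lay in or near Trpm6, Amd1, Lars2 and Ccdc34. The first, on chromosome 19 from 18890020 to 18890886, had a fold of 225.9 and a pileup of 938 fragments (95% Poisson interval 879 to 1000) and lay in the interior of Trpm6, a magnesium channel of the intestine and kidney, 2002 bp from its boundary. The next, on chromosome 10 from 40281386 to 40282371, reached a fold of 220.1 at 5616 bp from Amd1, which encodes the S-adenosylmethionine decarboxylase of polyamine synthesis. A site at 686 bp from a boundary of Lars2, the mitochondrial leucyl-tRNA synthetase, on chromosome 9 from 123461802 to 123462312 had a fold of 209.0. Interior sites followed in Ccdc34 (fold 205.7), Gtf2h2, a subunit of the repair and transcription factor TFIIH (189.1), Trip11 (179.9), Macrod2 (178.2) and Mapk8, the stress-activated kinase JNK1 (176.6). On chromosome X, the site from 96454952 to 96455887 had a fold of 197.2 and lay 111 bp from a boundary of Heph, the ferroxidase of intestinal iron export, inside Hsf3, which overlaps it. On chromosome 6, a site from 17593759 to 17594638 had a fold of 176.8 at 20292 bp from Met, the receptor of hepatocyte growth factor. The pileups of these 10 sites ran from 733 to 938 fragments. Regions prone to misplaced reads were not filtered out here, so technical signal among these sites is not excluded.

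Genes of the AP-1 and small Maf list were themselves surrounded by Fos summits. That list also holds Nfe2l2, and no mean was taken over AP-1 genes alone. Over the 16 genes of the AP-1 and small Maf list, which was fixed before the data were examined, distal summits (not at any boundary, within the gene or 50 kb of it) averaged 33.3 ± 18.4 (SD over genes), against 14.1 for random lists matched on gene density. The ratio was 2.36 and the adjusted p 0.0016, in the permutation test with 10000 random lists. Nfe2l2, the oxidative stress regulator NRF2, had the most distal summits, 66, and its strongest summit, with a fold of 135.4, lay 46 bp above its upper boundary on chromosome 2 (gene 75675513 to 75704663). Fosb had 56, and Maff, Fos and Atf3 had 48 each. Jund and Fosl2 had 46 each, Mafk 32, Junb 29, Fosl1 27, Jun 25 and Mafg 23. Batf3, Batf2, Batf and Jdp2 had 14, 13, 6 and 6. Batf acts mainly in lymphocytes, and Jdp2 represses AP-1 activity.

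A boundary summit was present at 14 of the 16 AP-1 list genes (87.5%, 64.0 to 96.5) against 61.9% of other protein-coding genes, a difference that did not pass the threshold (Fisher's exact test, two-sided, adjusted p = 0.0624, called Fisher p from here on). It passed in 3 of 9 alternatives. The difference from other genes, 25.6 percentage points in the main test, ran from 9.99 without regions wider than 3000 bp, where 11 of 16 genes had a boundary summit (adjusted Fisher p = 0.581), to 33.6 with boundaries of 2000 bp, where all 16 had one (0.0109). Batf and Batf3 lacked a boundary summit. The highest boundary fold was 182 at Fosl2, 170 at Maff, 151 at Atf3 and 150 at Jun, against 12 at Mafg and 4.81 at Jdp2. The median over the 14 genes with a boundary summit was 79.7. Strong sites also lay farther off. The strongest summit near Jund had a fold of 239.3 at 18033 bp below the gene, at the boundary of another gene, and that near Maff had 223.7 at 9730 bp above it, inside a neighbouring gene. Assignment of a summit to a gene rests on distance alone.

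The Fos gene, on chromosome 12 from 85473890 to 85477274, was the only protein-coding gene within its window and had 56 summits there, 8 at its boundaries, 3 inside it and 45 intergenic. Its strongest boundary summit had a fold of 61.8 and 256 fragments. Of the 45 intergenic summits, 4 had a higher fold than that. The summit at 85452034, which is 21856 bp below the gene, had a fold of 153.7 and 638 fragments (589 to 689), and those at 43620 bp and 18446 bp below it had folds of 151.5 and 139.5. On the other side, a summit 8772 bp above the gene had a fold of 101.3.

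**Figure D2:**
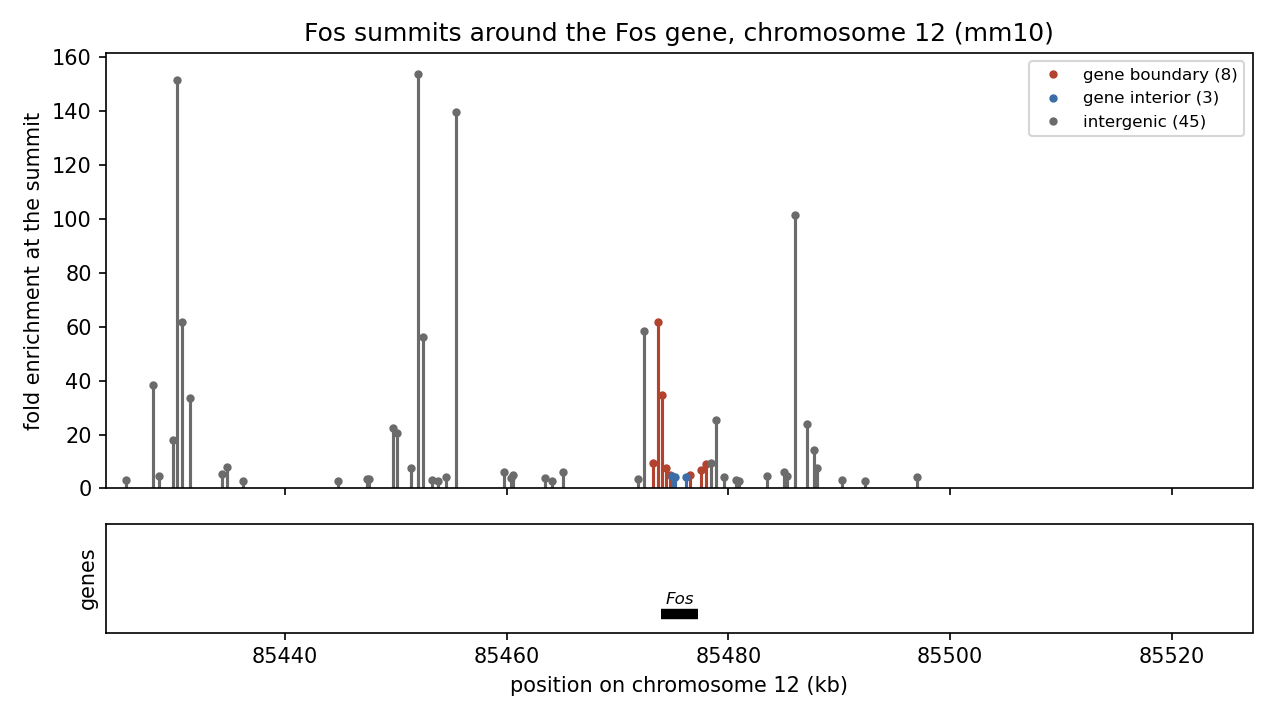
Fold enrichment at each Fos summit (vertical axis) along chromosome 12 from 85423890 to 85527274 in mm10 (horizontal axis, kb), with protein-coding genes drawn below and summits coloured by location class. The highest stems are the intergenic summits with folds of 153.7, 151.5, 139.5 and 101.3, above the 61.8 of the highest boundary summit of Fos.

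Genes that define the colonic epithelium carried the most Fos summits of the 24 lists. All 23 pan-epithelial and intestinal identity genes had a boundary summit (adjusted Fisher p = 0.000766), and their distal summits averaged 48.3 ± 16.9 (SD over genes) against 14.0 in matched random lists (ratio 3.45, adjusted permutation p = 0.0016). Cdh1, which encodes E-cadherin of adherens junctions, had 92 distal summits and a boundary fold of 70.5. The keratin genes Krt8 and Krt18, neighbours on chromosome 15, had 81 and 75 in overlapping windows, and the summit between them at 102016370 had a fold of 249.4. The boundary call ended without regions wider than 3000 bp, where the difference from other genes fell from 38.1 to 6.46 percentage points (adjusted Fisher p = 0.769), while the distal call held.

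Markers of mature colonocytes had distal summits at 32.2 ± 12.2 per gene (ratio 2.39, adjusted permutation p = 0.0016) and boundary summits at 17 of 18 genes (adjusted Fisher p = 0.00989). Slc16a1, the monocarboxylate transporter that carries butyrate and lactate, had 62, the mucin gene Muc13 had 50 and Ceacam1 had 49. The site 31157 bp below Ceacam1 had a fold of 323.5, but its nearest protein-coding gene was Cxcl17, at 17659 bp. Goblet cell genes averaged 27.9 ± 16.9 distal summits (ratio 1.95, adjusted permutation p = 0.0312), with a boundary summit at 14 of 14 (adjusted Fisher p = 0.00702). Creb3l1 had 69, Muc2, the main secreted mucin of the colon, 49 and Clca1 42. The distal call of the goblet list, an excess of 13.6 summits over random lists, ended with windows of 20 kb (excess 10.2, adjusted permutation p = 0.0568) and of 100 kb (excess 13.2, p = 0.107). With 1 summit per region the boundary calls of the colonocyte and goblet lists ended, with differences of 24.0 and 26.4 percentage points in place of 32.5 and 38.1 (adjusted Fisher p = 0.103 each), as they did without regions wider than 3000 bp for colonocytes (24.6, p = 0.114) and with −log10 q of at least 10 for goblet cells (23.0, p = 0.129).

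Stem cell and Wnt genes had 32.5 ± 26.5 distal summits (ratio 2.44, adjusted permutation p = 0.0024) and a boundary summit at 17 of 17 (adjusted Fisher p = 0.00427). Their counts ran from 3 to 109 with a median of 23. Lrig1, a receptor inhibitor that marks intestinal stem cells, had 109 distal summits, and the receptor tyrosine kinase gene Ephb2 and Prom1 had 75 and 57. These genes are long, and long genes had wider windows. Counted as the mean of windows around both gene boundaries, the excess of the stem list over random lists was 9.96 summits in place of 19.2, still past the threshold (adjusted permutation p = 0.0016).

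Immediate-early genes other than AP-1 were also rich in summits, at 27.4 ± 15.4 distal summits (ratio 2.04, adjusted permutation p = 0.00768) and 18 of 19 genes with a boundary summit (adjusted Fisher p = 0.00702), Egr2 being the exception. Btg2, an antiproliferative target of p53, had 66 distal summits, the orphan nuclear receptor gene Nr4a1 54 and Klf6 43. The highest boundary fold of Klf6 was 126 and that of Nr4a1 10.8. The distal excess over random lists went from 14.0 summits to 5.41 with 1 summit per region (adjusted permutation p = 0.0597) and to 8.32 with windows of 20 kb (0.0569), which ended the call. Fewer summits are counted in both settings by construction. The boundary call ended without regions wider than 3000 bp, where its difference fell from 32.8 to 14.9 percentage points (adjusted Fisher p = 0.392).

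Genes of epithelial inflammation and injury had boundary summits more often than other genes, but no distal excess that passed the threshold. The boundary comparison was not matched on gene activity, and the other genes include olfactory receptor genes, with a boundary summit at 18 of 1110. Housekeeping genes had one at 20 of 20, so a boundary excess does not set these lists apart from active genes in general. The inflammatory list had 20 of 23 genes with a boundary summit (adjusted Fisher p = 0.0297), without Lcn2, Reg3b and Cxcl2, and 23.0 ± 12.9 distal summits (ratio 1.59, adjusted permutation p = 0.0624). Its distal excess, 8.54 summits, passed in 7 of 14 alternatives, with 11.4 summits for random lists matched on gene length as well (adjusted permutation p = 0.00096) and 9.78 for windows around both boundaries (0.00206), and its highest adjusted p was 0.211, with windows of 20 kb. Tnip1 had 52 distal summits, Socs3, the feedback inhibitor of STAT3 signalling, 44 and Pigr, the transporter of IgA across the epithelium, 41. Saa and Reg3 genes are paralogs at shared loci, and read placement among them was not recorded in the sources used here. The boundary call of this list held in 3 of 9 alternatives, the fewest of any called list. Its difference from other genes, 25.01 percentage points in the main test, was 26.7 with 14 members among genes with boundaries apart (adjusted Fisher p = 0.11), 23.9 without regions wider than 3000 bp (0.0528), 23.3 with 1 summit per region (0.0752), 20.6 with boundaries of 2000 bp (0.0827), and 19.2 and 18.4 with −log10 q of at least 5 and 10 (0.11 and 0.119).

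The injury and fetal-like list had boundary summits at 21 of 24 genes (adjusted Fisher p = 0.0245), all but Anxa10, Spp1 and Msln, and 18.0 ± 12.7 distal summits (ratio 1.30, adjusted permutation p = 0.438). S100a6 had a boundary fold of 280, with 1165 fragments (1099 to 1234), and the laminin gene Lamb3 an interior fold of 191. Itga2 and S100a6 had 35 distal summits each and Lamb3 36. YAP/TEAD target genes had boundary summits at 14 of 15 (adjusted Fisher p = 0.0275) and 24.5 ± 15.7 distal summits (adjusted permutation p = 0.084), with 53 at Wwc1, 48 at Tead1 and 46 at Crim1. Interferon and antigen presentation genes had boundary summits at 15 of 16 (adjusted Fisher p = 0.0216), all but Ciita, and 16.1 ± 12.1 distal summits (adjusted permutation p = 0.777), led by Irf8 with 47 and Irf1 with 37. The boundary calls of the injury and YAP lists held in 5 and 6 of 9 alternatives and ended, among others, with −log10 q of at least 10, with differences of 19.5 and 24.5 percentage points in place of 25.6 and 31.4 (adjusted Fisher p = 0.0967 and 0.0978). The interferon call ended among genes with boundaries apart (0.0696), where 6 of 6 remaining genes had a boundary summit and the difference from other genes was 48.1 percentage points against 31.8 among all 16.

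Housekeeping and proliferation genes had boundary summits at every member, 20 of 20 (adjusted Fisher p = 0.00109) and 15 of 15 (adjusted Fisher p = 0.00548). Their distal summits averaged 17.5 ± 14.3 and 18.8 ± 14.3 and did not pass the threshold (adjusted permutation p = 0.561 and 0.464). Actb, the cytoplasmic actin, had 40 distal summits, among them a site 13020 bp above the gene with a fold of 344.2. Ywhaz had 59. Among proliferation genes the replication clamp Pcna had 53, Birc5 41 and Aurkb 33.

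**Figure D3:**
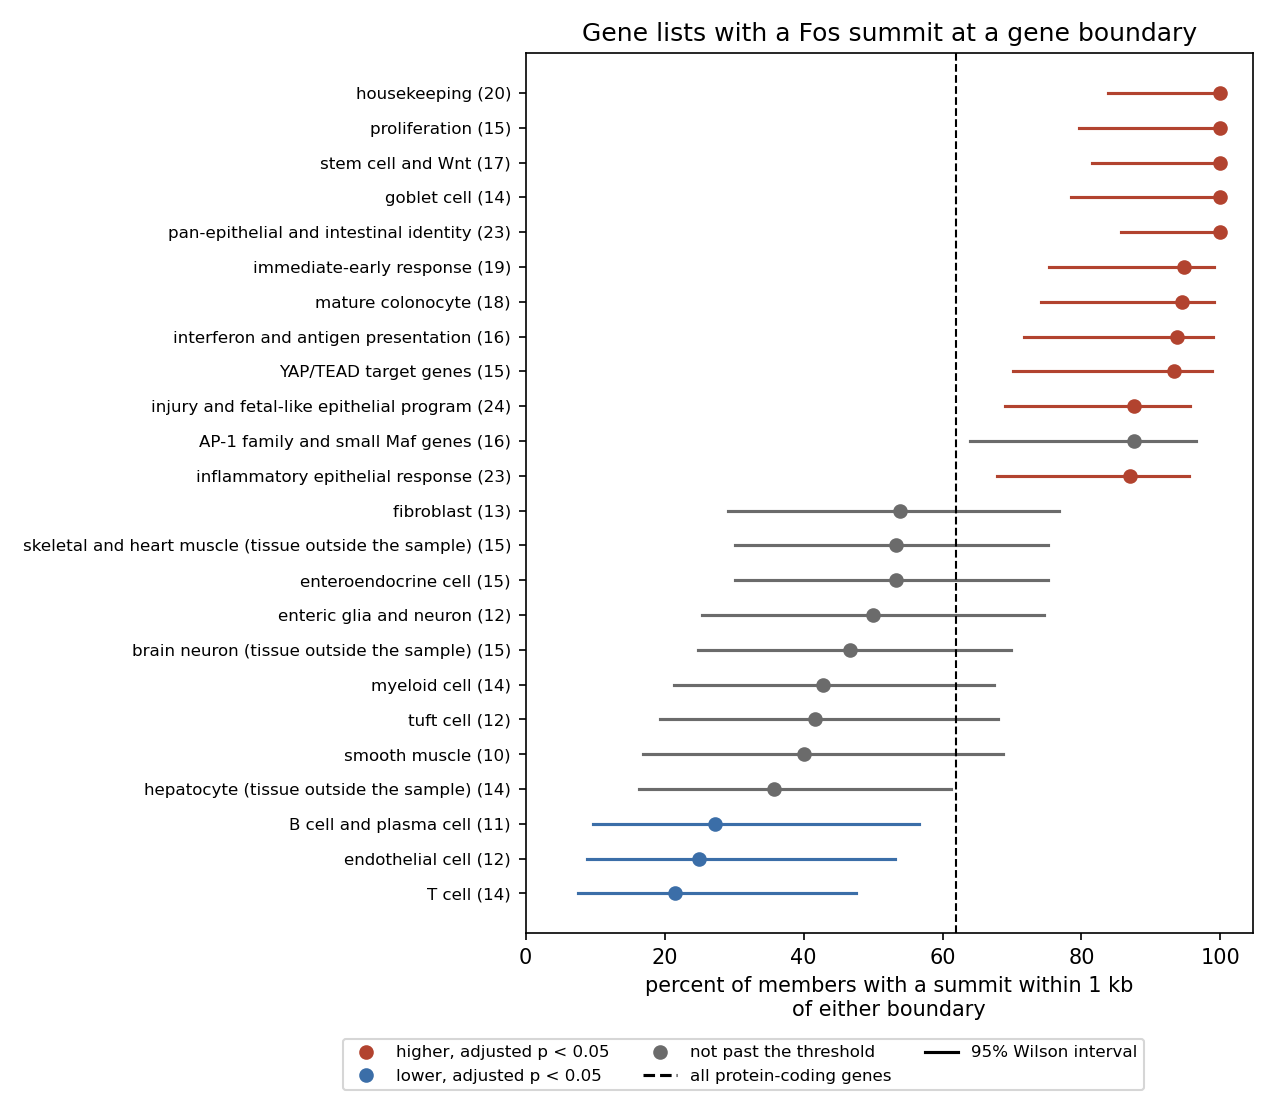
Percent of genes with a Fos summit within 1 kb of either boundary (horizontal axis) for the 24 gene lists (vertical axis, number of genes in brackets), with 95% Wilson intervals; the dashed line is the 62.0% of all 21627 protein-coding genes. In 11 lists the share is higher and in 3 lower at an adjusted p below 0.05.

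Markers of the rarer epithelial cell types passed neither main test. Enteroendocrine genes had boundary summits at 8 of 15 (adjusted Fisher p = 0.596) and 9.93 ± 8.23 distal summits (adjusted permutation p = 0.649), with Chga, Gcg and Pyy among those without a boundary summit. The highest counts were 26 at Pax6, 24 at Chga and 23 at Cck. Tuft cell genes had boundary summits at 5 of 12 (adjusted Fisher p = 0.293) and 18.0 ± 14.1 distal summits (adjusted permutation p = 0.546), with 53 at Sh2d6 and 30 at Trpm5. With −log10 q of at least 10, 2 of 12 tuft cell genes had a boundary summit. The difference from other genes was then -38.9 percentage points in place of -20.3 and passed the threshold (adjusted Fisher p = 0.019). The differences between these lists and the colonocyte or goblet list were not tested.

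Of the 7 lists of immune and stromal cells, 3 had fewer genes with a boundary summit. The share was lower than in other genes for T cell genes (3 of 14, adjusted Fisher p = 0.011), endothelial genes (3 of 12, adjusted Fisher p = 0.0275) and B and plasma cell genes (3 of 11, adjusted Fisher p = 0.0451). Cd3e, Cd3d, Cd3g and Cd8a had none, nor had Cd79a and Cd79b, nor the endothelial genes Pecam1, Cdh5 and Kdr. Sdc1, which plasma cells and epithelium both express, had a boundary fold of 72.4 and 45 distal summits. The T cell call held in all 9 alternatives, the B and plasma cell call in 6 and the endothelial call in 5. The B and plasma cell difference from other genes went from -34.7 percentage points to -2.76 with boundaries of 2000 bp, where 7 of 11 genes had a summit (adjusted Fisher p = 1), to -18.6 with 9 members among genes with boundaries apart (0.462) and to -32.1 with 1 summit per region (0.103). The endothelial difference went from -37.0 to -24.7 (0.207), -18.6 (0.462) and -34.4 (0.0572) in the same order, and to -33.8 without regions wider than 3000 bp (0.084). Myeloid (6 of 14, adjusted Fisher p = 0.241), fibroblast (7 of 13, 0.596), smooth muscle (4 of 10, 0.26) and enteric glia and neuron genes (6 of 12, 0.446) did not pass. The smooth muscle difference, -22.0 percentage points in the main test, passed at -39.1 with −log10 q of at least 5 (adjusted Fisher p = 0.0336) and -35.6 with at least 10 (0.0482).

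Distal summits around these 7 immune and stromal lists averaged from 7.42 for glia and neuron genes to 18.4 for smooth muscle genes, and none passed the threshold (adjusted p from 0.306 to 0.884). T cell genes averaged 12.1, B and plasma cell genes 12.7, myeloid genes 13.4, fibroblast genes 8.54 and endothelial genes 14.3. Single members had many, such as Lck with 34, Eng with 43, Pdgfrb with 40, Synpo2 with 52 and C1qb with 27. Syt1 had 20, but in a wide window, since the gene runs from 108497650 to 109010980 on chromosome 10. The strongest site near Pdgfrb, with a fold of 120.7, lay at the boundary of another gene and was also the strongest near Camk2a.

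The lists for tissues outside the sample served as background, and none of the 3 passed a test. Boundary summits were present at 5 of 14 hepatocyte genes (adjusted Fisher p = 0.081), 8 of 15 skeletal and heart muscle genes (0.596) and 7 of 15 brain neuron genes (0.345), among them Snap25, which is also in the glia and neuron list. Distal summits averaged 8 ± 10.6, 12.1 ± 14.4 and 16.6 ± 14.8 (adjusted permutation p = 0.264, 0.696 and 0.649). Tat, Tnnt2 and Rbfox3 had the most distal summits of these lists, 35, 49 and 45, with highest boundary folds of 38.5, 11.3 and 3.61. Rbfox3, from 118489760 to 118911597 on chromosome 11, is long, and its window was wide. The boundary results depended on the settings. The hepatocyte difference from other genes was -26.3 percentage points in the main test, -30.5 with −log10 q of at least 5 (adjusted Fisher p = 0.0415) and -16.4 with boundaries of 2000 bp (0.41). The brain difference was -15.3 in the main test, -39.1 with −log10 q of at least 5 (0.00964) and of the opposite direction, 6.94, with boundaries of 2000 bp (0.898). Among their members with a boundary summit (5, 8 and 7 genes) the median highest boundary fold was 14.0, 11.3 and 3.85. Epithelial lists lay on both sides of these values, with 70.5 in the pan-epithelial, 37.0 in the colonocyte, 17.8 in the stem, 10.3 in the goblet, 6.13 in the enteroendocrine and 5.05 in the tuft cell list. Over all 24 lists, 6 had more distal summits than matched random lists and 0 had fewer in the permutation test, and at an unadjusted p below 0.05 the counts were 8 and 0. Genes are not replicates, so these p-values concern this peak list and not a population of animals.

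**Figure D4:**
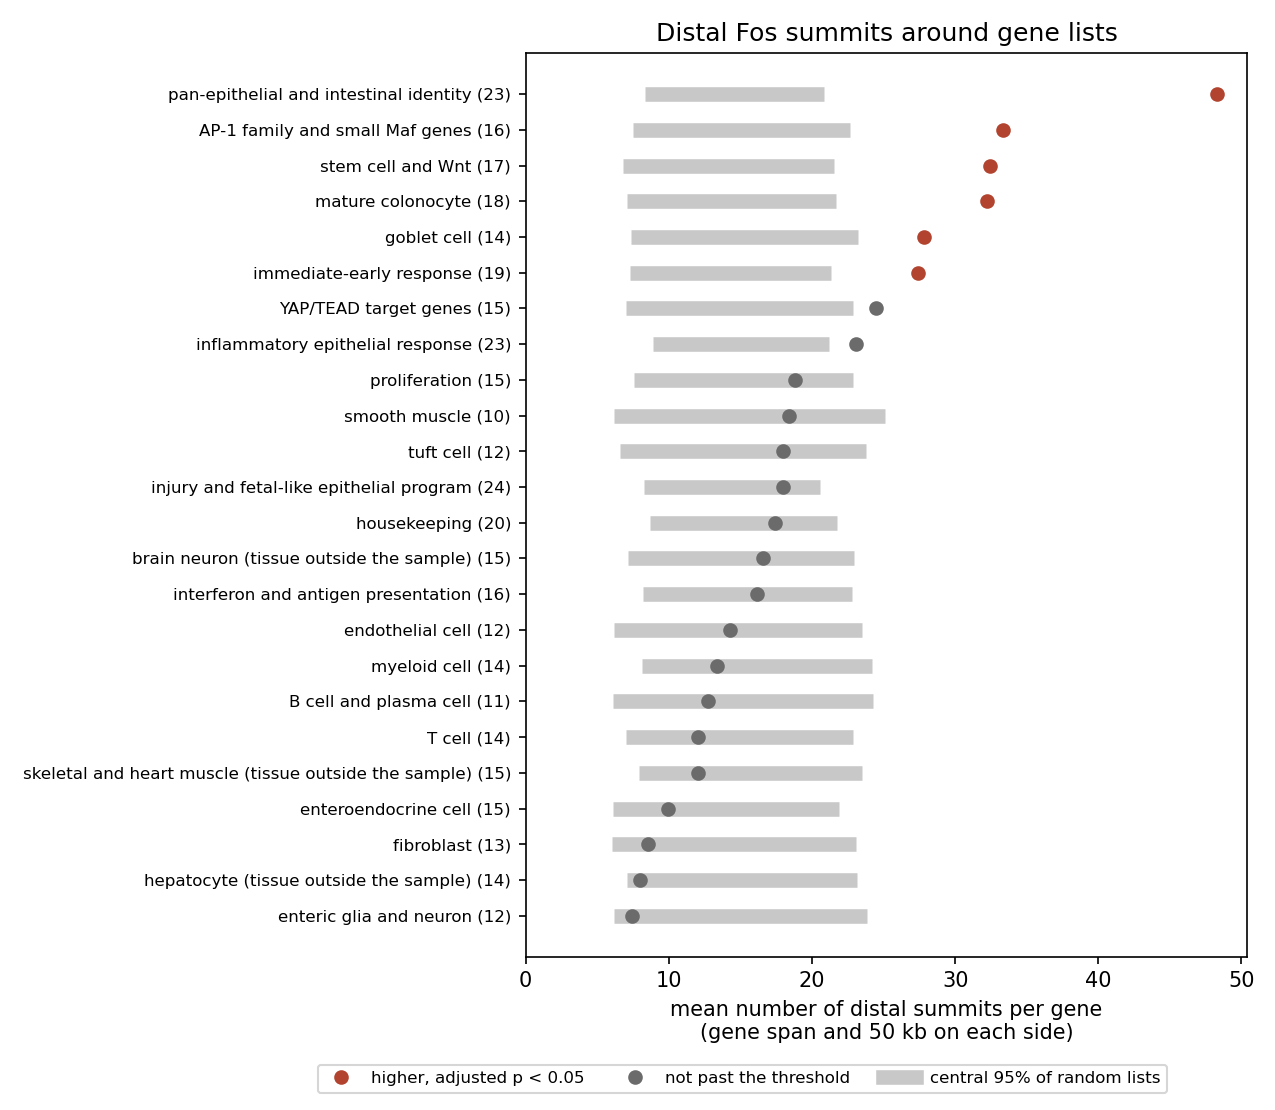
Mean number of distal Fos summits per gene (horizontal axis) for the 24 gene lists (vertical axis, number of genes in brackets); points are list means and grey bars hold the central 95% of 10000 random lists matched on gene density. The 6 lists past the threshold lie between 27.4 and 48.3, above their grey bars.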

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

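The test in this part was chosen after the result was seen. The region on chromosome 17 from 39843002 to 39848971 belongs to no list or gene compared above and carried some of the strongest signal of the whole peak list, with 10 summits, a highest fold of 526.5 and 2188 fragments. It holds the annotated 18S ribosomal RNA pseudogene Rn18s-rs5 and the lower end of the noncoding gene AY036118. Its lowest summit, with a fold of 229, lay at the 99.6th percentile of the lowest summits of the 279 regions with at least 10 summits, whose median was 3.61. Such uniformly high signal is consistent with reads from the many ribosomal DNA copies being placed on this copy, a technical candidate explanation. Fos binding at ribosomal DNA stays open, since no control library was used here, and no biological explanation was tested.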

How the results depend on the processing

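No paired analysis was possible because the peak list holds no value per library, which also kept out the healthy against recovered comparison, leaving out replicates and other splits of the samples. Not run for want of a genome sequence were all motif alternatives. Matching on density and length together, windows around both boundaries, boundaries apart, 1 gene per locus and leaving out the widest and ribosomal regions were chosen after seeing the data. Over the alternatives, single lists in the distal test kept direction and side of the threshold 308 times, gained a call 9 times, lost it 4 times and changed direction 15 times. In the boundary test these numbers were 172, 11, 27 and 6. The distal calls of the pan-epithelial, colonocyte, stem and AP-1 lists held in all 14 alternatives (highest adjusted p 0.0048, 0.0168, 0.0329 and 0.036), and the boundary calls of the stem, proliferation, housekeeping and T cell lists in all 9. The highest fold near a named gene moved beyond its counting interval 93 times and stayed within it 587 times. Both limits of −log10 q, 1 summit per region and autosomes only keep the strongest summits by construction, and all 85 genes stayed in each. With windows of 20 kb 33 genes moved and 52 stayed. With 100 kb these numbers were 30 and 55, and without regions wider than 3000 bp 29 and 56. The cause of each change was not tested unless stated. Depth per library is unknown, and 10 fragments was the least that gave a call.

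With −log10 q of at least 5, 19.2% of summits lay at boundaries, the enrichment was 6.32, and 6 lists were lower in the boundary test, smooth muscle, hepatocyte and brain genes among them. With at least 10, fewer summits remain by construction, 106321 in 65166 regions. Of these 21.1% lay at boundaries, the enrichment was 6.96, the pileup ratio 1.42, and 7 lists were higher and 7 lower, among these the former 3 and tuft cell genes. With 1 summit per region there are 108406 summits by construction, 13.2% at boundaries, an enrichment of 4.36, a pileup ratio of 2.92, and 6 lists higher and 1 lower. Without regions wider than 3000 bp, 16.8% lay at boundaries and 6 lists were higher. Boundaries of 500 bp gave 11.1%, 7.04 and a pileup ratio of 2.32, and boundaries of 2000 bp gave 24.9%, 4.34 and 1.36 with 1 list lower. Among genes with boundaries apart 1 list was lower. With windows of 20 kb 1 list, hepatocyte genes, was lower in the distal test (adjusted p 0.0211, range over its alternatives 0.0211 to 0.484).

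Direction changed only in lists that did not pass the same test in that setting. Boundary differences became 0.273 points for enteroendocrine and for muscle genes and 6.94 for brain genes with boundaries of 2000 bp, and 1.91, 2.61 and 10.6 points for enteroendocrine, muscle and myeloid genes with boundaries apart. Distal differences from random lists for endothelial genes became -1.06 with 20 kb, -2.28 matched on length alone and -1.24 matched on both. Brain genes gave -0.00525 with −log10 q of at least 10, -0.449 matched on length alone and -0.483 matched on both. With 100 kb, enteroendocrine genes gave 2.86, T cell 3.34, B and plasma cell 0.352 and myeloid genes 3.39. Myeloid genes gave 0.556 matched on length alone, enteroendocrine genes 0.849 matched on both and 0.979 with windows around both boundaries, where B and plasma cell genes gave 0.68, and muscle genes 0.11 with 1 gene per locus.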

Other observations

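The tests of fragment coverage on chromosome X and of weak summits in this part were chosen after the results were seen, as were the gene families. Among the Hox clusters, which set position along the body axis, the 11 Hoxa genes averaged 69.4 ± 17.3 distal summits (SD over genes), the 10 Hoxb genes 48.9 ± 21.4, the 9 Hoxd genes 35.7 ± 11.2 and the 9 Hoxc genes 23.7 ± 6.28, against 14.2 over all protein-coding genes. Genes of a cluster lie in overlapping windows, and no comparison with random lists of like gene density was made. Among genes of at most 50 kb, Hoxa9, Hoxa10, Hoxa11 and Hoxa13 had 84, 82, 82 and 81. The most, 154 and 145, lay around Mroh2a and Hjurp on chromosome 1, next to the Ugt1a genes of glucuronidation, of which Ugt1a2 had 113 and Ugt1a1 had 110. A region of 11201 bp there held 25 summits, with a highest fold of 9.14. Other genes with many distal summits were Krt8 with 81, the nuclear lamin gene Lmna with 81, Ezr, an actin linker of microvilli, with 79, and the tetraspanin gene Cd9 with 78.

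The widest region, 17879 bp on chromosome 19 from 5832921 to 5850799, held 37 summits up to a fold of 249.9 and overlapped Neat1, the noncoding RNA of paraspeckles. Others overlapped Plec (15096 bp, fold 379.6), Zfp36 (13888 bp, fold 141.0), a locus of Mirlet7b and Mirlet7c-2 (13026 bp, fold 85.6), Cant1 (12560 bp, fold 172.7) and Sdc4 (10179 bp, fold 235.5). The region of 16168 bp inside Sfi1 on chromosome 11 had 33 summits and a highest fold of 66.6. Technical signal is not excluded at these wide regions either. The summit of highest fold in the list, 671.6 with 2791 fragments, lay on chromosome 2 in a region from 32470390 to 32472670, 15698 bp from Naif1, and the next, 532.3, lay 19820 bp from Ets2.

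Boundary summits were rare at sensory receptor genes. Olfactory receptor genes had one at 18 of 1110 (1.62%, 95% Wilson interval 1.03 to 2.55) and vomeronasal receptor genes at 4 of 353 (1.13%, 0.442 to 2.88). Alpha-defensin genes, made by Paneth cells of the small intestine, had one at 0 of 29 (0 to 11.7). Genes whose symbols begin with Rpl or Rps and a digit, most of them ribosomal protein genes, had one at 88 of 97 (90.7%). Other genes with such symbols were not removed. Proteasome subunit genes had one at 37 of 40 (92.5%). Of the 408 tRNA genes, 52.7% (47.8 to 57.5) had a summit within 500 bp, and of the 341 at least 2000 bp from a coding gene boundary, 45.7% (40.5 to 51.1). Away from coding gene boundaries the share was 46.5% for lncRNA genes, which are far longer (median 8405 bp against 72 bp), 12.7% for miRNA genes, 8.43% for snoRNA genes and 7.14% for snRNA genes.

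Chromosome X had few summits, 14.3 per 1 Mb bin against 73.5 on autosomes. The summits it had showed a median pileup of 29 against 27 and a 90th percentile of 132.7 against 157. Both values cover only summits past the same lower limit of calling, so they do not compare coverage. Lower gene content is argued against as the whole cause, since X bins held 0.238 (95% bootstrap interval 0.197 to 0.281) times the summits of autosomal bins with the same number of genes. Lower coverage, as with 1 copy of X per cell, is argued against as the whole cause as well. It would at most halve pileups, yet X bins held 0.375 (0.321 to 0.443) times the autosomal summits of at least 20 fragments, which is 2 times the lowest pileup. Loss of reads in repeats of X and fewer Fos sites on X stay open and were not tested, and the labels used here give no sex.

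Boundary summits at 20 genes of the liver, muscle and brain lists, tissues outside the sample, had highest folds from 2.89 to 43.5 with a median of 8.66. A shared boundary with another protein-coding gene is argued against as the source for most. Of the 20, 10.0% (95% Wilson interval 2.79 to 30.1) had all their boundary summits within 1000 bp of another such gene's boundary, Actn3 and Rbfox3. Neighbours farther off and noncoding genes were not tested as owners. Whether they are summits close to the lower limit of calling cannot be told apart from real sites with this number of genes. Of the 20, 30.0% (14.5 to 51.9) had under 20 fragments at their highest boundary summit, among them Alb with 19, while Tat had 159 and Ckm 129. Of all autosomal summits, 64.2% had at least 20 fragments, but that share counts single summits of every class. The highest boundary summits of other genes were not counted in this way, so whether low counts are particular to these genes was not tested. Apob is also expressed by intestinal epithelium, and Snap25 (fold 7.94) is also in the list of enteric glia and neurons, so not every one of the 20 is foreign to the colon. No biological explanation was tested.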
